A study of Mus musculus with 4 samples.

How the data were processed

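MicroRNA (miRNA) levels were measured on 4 one-colour (Cy3) Agilent arrays, 1 per placenta. The placentas were collected at embryonic day 11.5 (E11.5) from embryos made by in vitro fertilisation, and the decidua, the maternal lining, was removed before RNA isolation, per the labels' protocols. The 4 samples carry the same labels apart from their replicate number, so they form 1 group. The protocols mention wild-type and miRNA-deleted mice, but the labels give no genotype for any of these samples, and none was inferred. No group comparison, and so no replicated test between groups, was possible. Nothing in the labels says that the placentas came from separate litters, so they may not be independent. Each placenta was measured on 1 array, so the spread between placentas may be partly technical.

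Per the file headers, the authors extracted the spot signals with Agilent Feature Extraction 10.5.1.1, the program also named in the submitters' processing notes. The deposited spot files hold intensity values on a linear scale, with background and a spatial trend subtracted, negative values kept, and no normalization between arrays. They also hold flags of 0 or 1 for spots well above background, outliers and saturation. The authors' value table for the series holds intensity values of the same arrays, 1 row per miRNA and on a linear scale. Of its 263 mouse rows above 0.1 on any array, 249 could be matched by name and value to a miRNA of the spot files. Of the 942 values compared, 66.3% lay within 1% of the total signal per miRNA in the spot files, and the median of each column was 0.1, the value given to most miRNAs. The table is therefore on the scale of the spot files and not centred, and how its values of 0.1 were assigned is not given in the sources used here. The genome build named for the array grid is mm9, per the file headers.

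Each array held 45440 miRNA spots, none saturated. Between 4.43% and 5.24% of them were flagged as outliers and left out. The remaining spots of a probe were averaged, then the probes of a miRNA (1 to 4 per miRNA). A miRNA was called detected on an array when at least 1 of its probes was well above background in over 0.5 of its spots. Because only 18.2% of the miRNAs were detected on all arrays, each array was divided by the 75th percentile of the miRNAs detected on all 4 arrays, floored at -4.83 on the log2 scale (the median over arrays of the lowest detected value) and converted to log2. The normalised signal is this log2 value. Probes differ in labelling and binding, so the normalised signals of different miRNAs do not rank their abundance. A signal share is the percentage of the array's summed mouse miRNA signal, with negative values set to 0. It is a share of fluorescence and not of molecules.

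A total of 19 lists of miRNAs were fixed by name before the data were examined. They cover the families of the Sfmbt2 cluster (miR-297, miR-466, miR-467 and miR-669), other placental, imprinted or widely expressed groups, and markers of other cell types. No list of decidual miRNAs was used. Membership of the Sfmbt2 list was by family name. Precursor positions were looked up in the RefSeq gene table of assembly GRCm38, used only to ask which precursors lie within the Sfmbt2 gene. Detection of each list with at least 3 measured members was set against all other mouse miRNAs with Fisher's exact test, two-sided, with Benjamini-Hochberg adjustment over 17 lists. This test runs across miRNAs, which are not independent replicates, since members of a cluster are transcribed together and probes of near-identical miRNAs can share target. For the 7 lists with at least 5 members detected on all arrays, the median deviation of the members from their means over the placentas was ranked among 10000 random lists of the same size matched on mean level. That rank describes these arrays and is not a test across placentas. In the list deviations, percentiles outside 2.5 to 97.5 were treated as shifted when alternatives were compared, a choice made after the data were examined.

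The list tests were tested on simulated data. A shift of 0.3 (log2) put on the 24 Sfmbt2-family members among 196 miRNAs in 1 array passed percentile 97.5 in 100% of 100 simulated sets, against 3% with no shift. A 3-fold higher odds of detection for 62 of 1079 miRNAs passed an unadjusted p of 0.05 in 96% of sets, against 3% with no difference. The simulations drew each miRNA independently, with 1 common SD for the levels. They do not cover detection or shifts shared between list members, so the 3% need not hold for the real lists. The simulated shift was also larger than any Sfmbt2 shift given below relative to all detected miRNAs.

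The miRNAs named in the text were chosen by a rule written before the data were examined. Among miRNAs detected on all 4 arrays, these were the 12 Sfmbt2-family members with the highest mean, 3 of each other list, the 5 with the highest mean outside the lists and the 5 with the largest SD. Names chosen later are identified as such. Alternatives covered the detection call, the signal column, background correction, scaling between arrays, the probes used, the authors' value table and leaving out each placenta. The planned normexp correction (limma 3.58.1 in R 4.3.3, offset 50) used the median spot signal, since the files hold no mean spot signal, and that choice came after the files were seen. Its offset is added to every spot, those of undetected miRNAs included. By construction it raises the shares of lists with many undetected members and lowers those of bright lists. It also shrinks log2 differences between arrays for dim miRNAs. Per the file headers, placentas 1 and 2 were read in 1 scan and placentas 3 and 4 in another. The slide was not named for every array, so the scan was used as the batch. Calculations used Python 3.11.15, numpy 2.4.6, pandas 2.3.3 and scipy 1.17.1. The number of arrays limits the precision. Probes for 57 viral miRNAs were left out of all comparisons.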

Results

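The miRNA content of the mouse placenta was measured at E11.5, to find which miRNAs were present, among them those of the rodent-specific cluster within the gene Sfmbt2. There were 4 placentas, each on its own array. The arrays carried probes for 1079 mouse miRNAs. The number of spots well above background ran from 6484 to 7070 per array, out of 45440. Between 18.4% and 20.1% of the miRNAs were detected per array, and 196 (18.2%) were detected on all 4. A further 33 were detected on some arrays only. Across the detected miRNAs, the Pearson correlation between pairs of arrays ran from 0.978 to 0.995, and no pair held identical values. These correlations are across miRNAs, which are not independent replicates. The median SD between placentas was 0.19 (log2, n = 4), and 0.12 without placenta 4. Within the 2 scans in which the arrays were read, the pooled SD had a median of 0.18.

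miRNAs of the Sfmbt2 families were detected more often than other miRNAs. Of the 62 members on the array, 24 (38.7%) were detected in all 4 placentas, against 172 of 1017 (16.9%) for the rest, an odds ratio of 3.10 (Fisher's exact test, adjusted p = 0.00095). By family, 2 of 4 measured members of miR-297, 7 of 23 of miR-466, 7 of 12 of miR-467 and 8 of 23 of miR-669 were detected. The 62 probe sets together took 5.93% ± 0.26 (SD, n = 4) of the miRNA signal, with 3.22% ± 0.22 on miR-467, 1.39% ± 0.075 on miR-669, 1.13% ± 0.092 on miR-466 and 0.188% ± 0.022 on miR-297. The reference annotation places 71 precursors of these families within Sfmbt2 and 10 elsewhere. Of the 49 measured members whose precursors all lie within Sfmbt2, 18 were detected, and on these alone the odds ratio was 2.78 (Fisher's exact test, adjusted p = 0.015). Many members differ by few bases, so the signal of a single member may include that of its relatives.

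**Figure D1:**
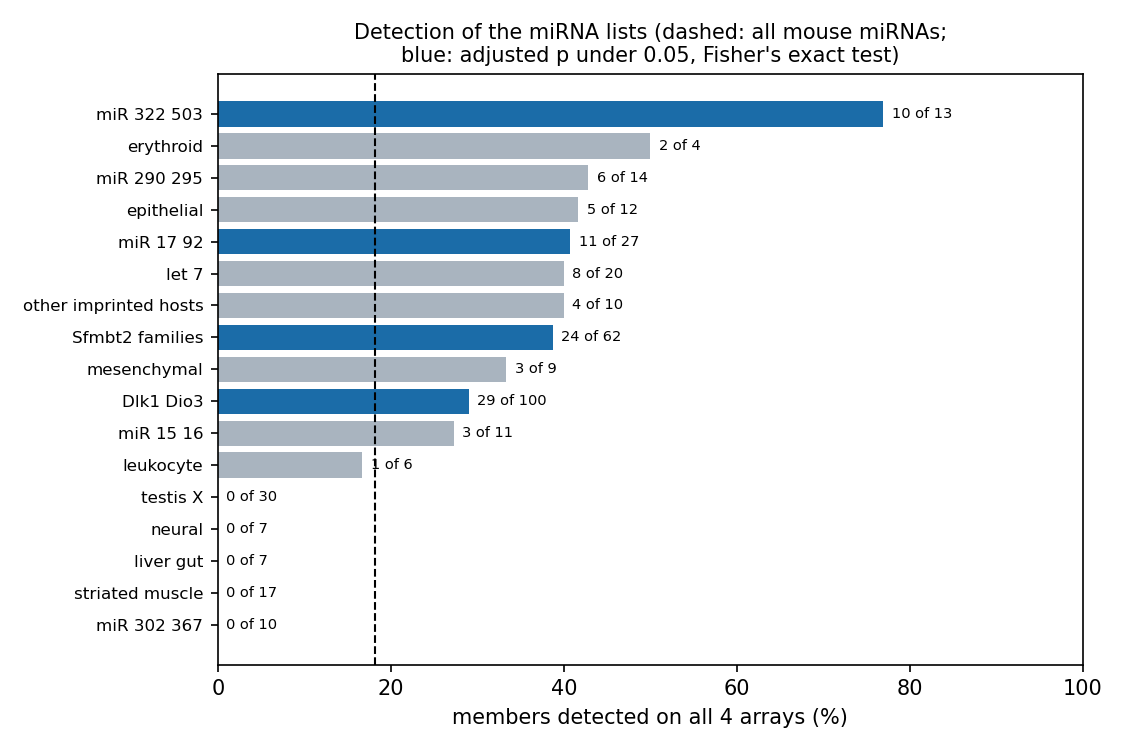
Percentage of the measured members of each miRNA list detected on all 4 arrays (x axis, %), with the counts beside the bars and 1 bar per list on the y axis. The dashed line marks 18.2% for all mouse miRNAs, and blue bars have an adjusted p under 0.05 (Fisher's exact test), among them the Sfmbt2 families with 24 of 62.

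The detected members of these families had a median SD of 0.14 between placentas, against 0.19 for all detected miRNAs, a difference that was not tested. Both values include placenta 4, where the scaling left all detected miRNAs at -0.22 and these members at -0.15 (median deviation, log2). Without placenta 4, the median SD of all detected miRNAs was 0.12. The gap therefore does not show that these families vary less between placentas. miR-467a-3p had a normalised signal of 2.93 ± 0.11 (SD, n = 4), miR-669f-3p of 1.92 ± 0.13 and miR-466b-3p of 1.60 ± 0.11. miR-467b-5p stood at 1.001 ± 0.14, miR-467a-5p at 0.70 ± 0.14, miR-467d-3p at 0.40 ± 0.20 and miR-467e-5p at 0.36 ± 0.11. miR-467c-5p stood at -0.22 ± 0.12, miR-297c-5p at -0.66 ± 0.23 and miR-669b-5p at -0.96 ± 0.20. The precursors of these 10 miRNAs lie within Sfmbt2. miR-669n, whose precursor lies elsewhere, had the smallest SD of the detected members (-0.38 ± 0.039). miR-466i-5p, also encoded outside Sfmbt2, had the largest (0.23 ± 0.66), with 0.47 and 1.05 in placentas 1 and 2 and -0.41 and -0.20 in placentas 3 and 4. Of the 24 detected members, 15 had an SD below the median of all detected miRNAs, with placenta 4 included in both.

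**Figure D2:**
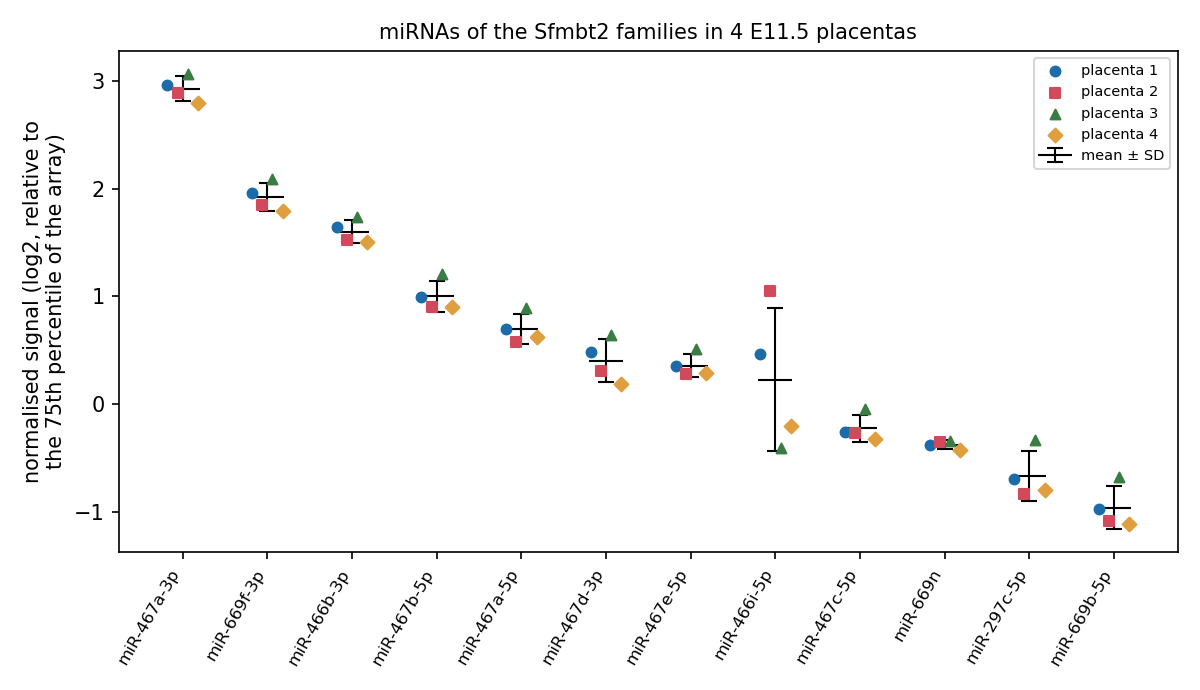
Normalised signal (y axis, log2 relative to the 75th percentile of each array) of the 12 named miRNAs of the Sfmbt2 families (x axis), with 1 point per placenta and the mean ± SD. miR-669n has the smallest SD, 0.039, and miR-466i-5p the largest, 0.66.

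Each miRNA hairpin can give a mature product from its 5' or its 3' arm. Both arms were on the array for 18 hairpins of the Sfmbt2 families. Of these, 2 (miR-466i and miR-467a) had both arms detected in all placentas, 6 had the 5' arm alone, 3 the 3' arm alone and 7 neither. Among 366 other hairpins, 10 had both arms detected, 49 the 5' arm alone and 60 the 3' arm alone. The share with both arms, among hairpins with any arm detected, was 18.2% for the Sfmbt2 families and 8.40% for the others, which Fisher's exact test did not separate (p = 0.27).

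Other miRNA clusters known from placenta or early embryo were detected to differing degrees. The X-linked cluster of miR-322 and miR-503 had 10 of 13 members detected (odds ratio 15.8, Fisher's exact test, adjusted p = 9.4e-05). Over 7 alternatives the odds ratio was lowest, at 5.72 with 5 members detected, when every probe had to be above background (Fisher's exact test, adjusted p = 0.034, the highest, with 9.4e-05 the lowest). The list took 8.16% ± 1.15 (SD, n = 4) of the signal, and 4.81% with normexp correction. Its miR-322-5p stood at 4.65 ± 0.09, miR-503-5p at 3.34 ± 0.12 and miR-542-3p at -0.18 ± 0.14. The miR-17~92 cluster and its paralogs, linked with cell proliferation, had 11 of 27 detected (odds ratio 3.22, Fisher's exact test, adjusted p = 0.020). Among them were miR-19b-3p (2.19 ± 0.14), miR-20a-5p (2.12 ± 0.13) and miR-92a-3p (1.30 ± 0.15). With Feature Extraction's own detection call this list no longer passed (Fisher's exact test, adjusted p = 0.068, the highest of 7 alternatives, with 0.020 the lowest).

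The Dlk1-Dio3 cluster, in an imprinted region whose miRNAs are expressed from the maternal allele, had 29 of 100 members detected (odds ratio 1.99, Fisher's exact test, adjusted p = 0.020). It took 2.67% ± 0.17 (SD, n = 4) of the signal, and 5.83% with normexp correction, whose offset also raises the undetected members. miR-494-3p stood at 1.24 ± 0.19, miR-127-3p at -0.18 ± 0.22 and miR-154-3p at -0.31 ± 0.26. When every probe of a miRNA had to be above background, the list had 14 members detected and did not pass (Fisher's exact test, adjusted p = 0.38, the highest of 7 alternatives, with 0.018 the lowest). miRNAs of other imprinted hosts had 4 of 10 detected, which did not pass (Fisher's exact test, adjusted p = 0.15). They included miR-335-5p from Mest (-2.25 ± 0.22), miR-296-5p from the Nespas locus (-2.26 ± 0.25) and miR-675-3p from H19 (-2.71 ± 0.29).

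The cluster from miR-290 to miR-295, known from pluripotent cells and early trophoblast, had 6 of 14 members detected (Fisher's exact test, adjusted p = 0.067), with miR-292-3p at 1.12 ± 0.12, miR-295-3p at 0.96 ± 0.11 and miR-294-3p at 0.68 ± 0.11. The cluster of miR-302 and miR-367, also of pluripotent cells, had 0 of 10 detected (Fisher's exact test, adjusted p = 0.29). The let-7 family had 8 of 20 detected, which did not pass (Fisher's exact test, adjusted p = 0.0501) and passed when every probe had to be above background (adjusted p = 0.033, same test, the lowest of 7 alternatives, with 0.090 the highest). It included let-7a-5p (1.82 ± 0.11), let-7f-5p (1.70 ± 0.08) and let-7d-5p (1.22 ± 0.15). The miR-15/16 family had 3 of 11 detected (Fisher's exact test, adjusted p = 0.46), namely miR-16-5p (0.59 ± 0.22), miR-15b-5p (0.39 ± 0.29) and miR-15a-5p (-0.93 ± 0.29). miR-210-3p, which is induced by hypoxia, was detected in all 4 placentas at -1.96 ± 0.20.

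Markers of several other tissues were not detected on any array. These were the markers of striated muscle (0 of 17), nervous tissue (0 of 7), liver and gut (0 of 7) and the X-linked testis cluster (0 of 30). Detection was lower than for other miRNAs in the testis list (Fisher's exact test, adjusted p = 0.019), and did not pass in those of muscle (adjusted p = 0.10), nervous tissue or liver and gut (adjusted p = 0.41 for both). The testis list did not pass when every probe had to be above background (Fisher's exact test, adjusted p = 0.16, the highest of 7 alternatives, with 0.0060 the lowest). The epithelial list, the miR-200 family and miR-205, had 5 of 12 detected (Fisher's exact test, adjusted p = 0.10), with miR-200c-3p at -0.26 ± 0.32, miR-141-3p at -0.60 ± 0.36 and miR-205-5p at -2.64 ± 0.06. Endothelial miR-126-3p stood at 0.53 ± 0.15. Mesenchymal markers had 3 of 9 detected (Fisher's exact test, adjusted p = 0.29), namely miR-199a-3p (-1.06 ± 0.30), miR-199b-5p (-1.80 ± 0.39) and miR-199a-5p (-2.84 ± 0.34).

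Some blood markers were detected in all placentas, and their levels differed between them. Erythroid markers had 2 of 4 detected (Fisher's exact test, adjusted p = 0.24) and leukocyte markers 1 of 6 (adjusted p = 1, same test). miR-451a, abundant in red blood cells, had a normalised signal of 3.20, 4.50, 3.59 and 2.79 in placentas 1 to 4. miR-144-3p, made from the same precursor transcript, stood at -1.99, -0.82, -1.43 and -2.37, and leukocyte miR-142-3p at -2.16, -1.33, -1.94 and -2.53. The erythroid list took 4.67% of the signal in placenta 2, against 2.01%, 2.47% and 1.76% in placentas 1, 3 and 4. Its mean share of 2.73% was 1.59% with normexp correction.

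**Figure D3:**
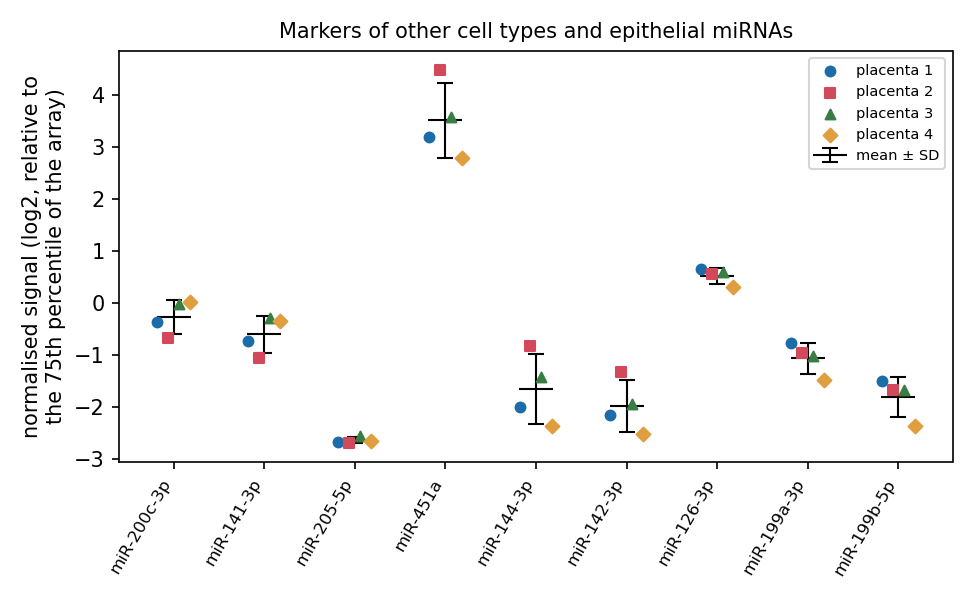
Normalised signal (y axis, log2 relative to the 75th percentile of each array) of epithelial, blood, endothelial and mesenchymal miRNAs (x axis), with 1 point per placenta and the mean ± SD. miR-451a, miR-144-3p and miR-142-3p are highest in placenta 2, at 4.50, -0.82 and -1.33.

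Outside the lists, the 5 miRNAs with the highest mean were miR-3963 (7.13 ± 0.15), miR-720 (5.44 ± 0.15), miR-5100 (4.54 ± 0.15), miR-5109 (4.31 ± 0.28) and miR-3968 (4.20 ± 0.17). They took 52.3% ± 1.18 (SD, n = 4) of the signal, with 29.9% on miR-3963 alone. miR-720 is a fragment of a transfer RNA and has been withdrawn from the miRNA registry. Without miR-3963 in the total, the Sfmbt2 families took 8.46% of the signal.

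The detected miRNAs with the largest SD were miR-721 (-0.97 ± 0.94), miR-211-3p (1.53 ± 0.81), miR-3082-5p (-2.20 ± 0.77), miR-451a (3.52 ± 0.73) and miR-714 (-2.92 ± 0.70). All of these but miR-451a were higher in both placentas of the first scan than in both of the second. miR-721 stood at -0.24 and -0.20 in placentas 1 and 2 and at -1.28 and -2.17 in placentas 3 and 4. In all, 12 of the 196 detected miRNAs differed by 2-fold or more between the highest and the lowest placenta.

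Some lists shifted together from placenta to placenta. The scaling left the median of all detected miRNAs at 0.03, 0.07, 0.10 and -0.22 (log2) from its mean in placentas 1 to 4, so list shifts are given relative to that median. Dlk1-Dio3 miRNAs lay above that median on both arrays of the first scan and below it on both of the second. Their shifts were 0.057 (26 of 29 members above) and 0.12 (28 above) in placentas 1 and 2, and -0.040 (23 below) and -0.11 (28 below) in placentas 3 and 4. These values lay at percentiles 97.0, 99.6, 3.14 and 2.20 of matched random lists. The cluster of miR-322 and miR-503 lay at -0.23 in placenta 2 (10 of 10 members below) and 0.28 in placenta 4 (10 of 10 above), below and above all 10000 random lists. The let-7 family lay at -0.10 in placenta 1 (8 of 8 members below, percentile 0.30), at -0.16 in placenta 2 (percentile 2.79, not past the lower bound of 2.5) and at 0.31 in placenta 4 (8 of 8 above), above all random lists. The epithelial list lay at -0.26 in placenta 2 (5 of 5 members below, percentile 0.31), at 0.14 in placenta 3 (4 of 5 above, percentile 99.1) and at 0.21 in placenta 4 (3 of 5 above, percentile 98.9). The shifts of the Sfmbt2 families were small, at 0.0056, -0.11, 0.057 and 0.076 in placentas 1 to 4, with percentiles of 60.1, 2.40, 99.2 and 94.1. For the cluster from miR-290 to miR-295 the 4 shifts ran from -0.020 to 0.049 and for miR-17~92 from -0.061 to 0.072, the latter in placenta 3 at percentile 97.6. Outside the miR-290 to miR-295 cluster, whose signs changed, the shifts in placentas 2 and 4 had the same sign with quantile scaling, normexp correction, negative controls subtracted and the brightness trend removed. Their sizes moved. With normexp, the shifts in placentas 2 and 4 were -0.089 and 0.12 for the cluster of miR-322 and miR-503, -0.042 and 0.013 for the epithelial list and 0.054 and -0.057 for Dlk1-Dio3, and the Sfmbt2 families lay at -0.037 in placenta 2. The epithelial list lay at 0.016 in placenta 3 with normexp, and Dlk1-Dio3 at 0.025 in placenta 1 and -0.018 in placenta 3. The let-7 shift in placenta 1 was -0.053 with negative controls subtracted. In placenta 2, let-7 lay at -0.082 with quantile scaling, -0.079 with negative controls subtracted and -0.089 with the trend removed, and the epithelial list at -0.45 with negative controls subtracted. For miR-17~92 the shifts under these settings ran from -0.055 to -0.019 in placenta 2 and from 0.000080 to 0.077 in placenta 4. miR-451a, miR-144-3p and miR-142-3p were highest in placenta 2 and lowest in placenta 4.

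**Figure D4:**
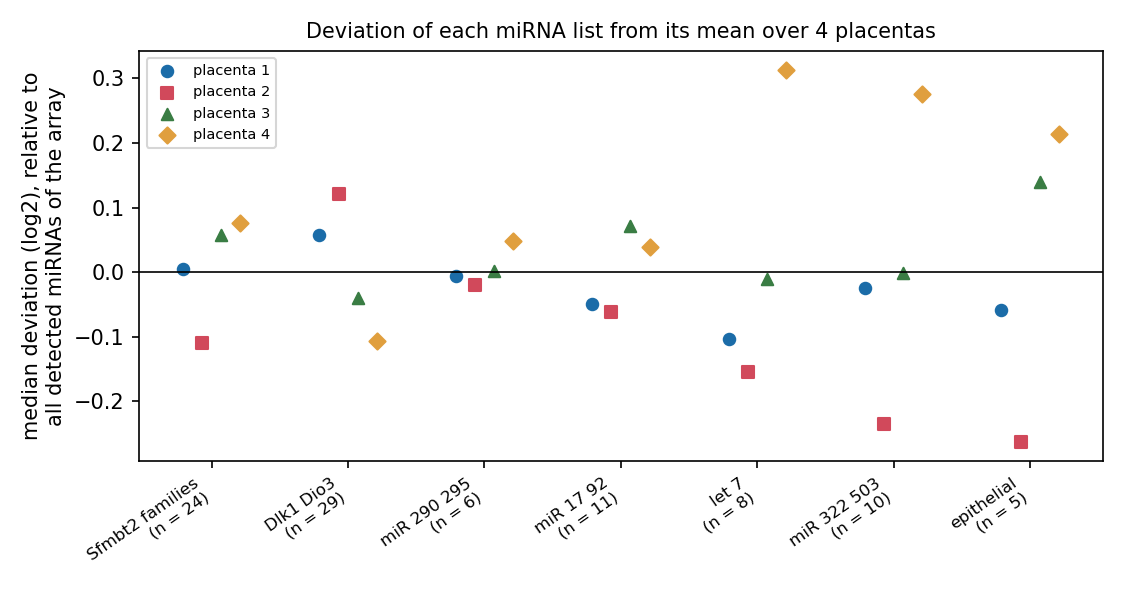
Median deviation (y axis, log2) of each list's detected members from their means over the 4 placentas, relative to all detected miRNAs of the array, for 7 lists (x axis, with the number of members), 1 point per placenta. The cluster of miR-322 and miR-503 lies at -0.23 in placenta 2 and 0.28 in placenta 4, and Dlk1-Dio3 at 0.12 and -0.11.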

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

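In this part, the comparison within a scan was chosen after the result was seen. In each of 90 sets of 4 values, the highest and lowest placenta were set against the others, and in 4 sets a placenta stood far apart, where about 4.5 would do so by chance.

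Leukocyte miRNAs took 0.165% of the signal in placenta 2, far from the 0.0730% to 0.0768% of the other placentas. Their mean share of 0.0973% ran from 0.0566% to 0.317% over 11 alternatives. The list includes miR-223-3p, detected on 3 arrays only and chosen here after its values were seen. It stood at -1.52 in placenta 2 and at -3.21, -3.57 and -3.35 in placentas 1, 3 and 4. The 3 erythroid and leukocyte miRNAs detected on all arrays (miR-451a, miR-144-3p and miR-142-3p) were highest in placenta 2. They were higher in placenta 2 than in placenta 1, read in the same scan, by a median of 1.17 (log2), over 2 times the median SD (0.39). An effect shared by both arrays of a scan would not give that difference. Placenta 2 was picked as the highest, so the sign of the difference was built in. The median SD is that of all detected miRNAs, whereas these 3 had SDs of 0.50 to 0.73. With the brightness trend removed, they were still higher in placenta 2 than in the others by a median of 0.93, against 1.11 before. That argues against scaling by brightness as the whole cause. More blood in that piece of tissue may explain the pattern, which was not tested apart from the pattern itself, and neither was any other biological explanation.

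miR-199a-5p lay at -3.35 in placenta 4, against -2.72 to -2.59 in the others, while its signal before scaling was 21.5 there and 24.0, 21.0 and 22.1 in placentas 1 to 3. The share of mouse miRNAs detected was 18.44% in placenta 3, against 19.9% to 20.1% in the others. The 75th percentile signal used for scaling was 218.98 in placenta 4, against 137.4 to 145.5 in the others.

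Among the probes for 57 viral miRNAs, which the report's comparisons leave out, 2 were detected on every array. The mouse cytomegalovirus miRNA mcmv-miR-M23-1-5p had a normalised signal of -0.77 ± 0.14 (SD, n = 4) and mcmv-miR-m88-1-3p of -1.45 ± 0.27. Their spot signals ran from 54.9 to 119 units, where the median of the negative control spots ran from -0.43 to 4.33. Whether these probes bound other RNAs could not be checked, so the signals do not show that viral miRNAs were present.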

How the results depend on the processing

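No paired analysis was possible because there is 1 group of placentas. The normexp, negative-control, brightness-trend and within-scan settings, and those leaving out miR-3963 from the total, undetected miRNAs or miR-466i-5p, were chosen after seeing the data. The Sfmbt2 families kept an odds ratio between 2.52 and 4.38 and an adjusted p under 0.05 (Fisher's exact test) in all 8 alternatives, and the arm comparison passed in 0 of 7. Requiring every probe to be above background left 110 detected miRNAs, fewer by construction. The Sfmbt2 share was 5.57% with the brightest probe alone, 5.33% for members inside Sfmbt2 and 8.46% without miR-3963. The median SD was 0.146 with normexp, 0.141 with quantile scaling and 0.131 with the brightness trend removed, and 0.123 to 0.229 leaving out each placenta, lowest without placenta 4. Total gene signal is nearly proportional to the main signal here and tests little. Shares do not change with a factor per array, so the scaling alternatives were not run for them, nor was the slide as a block, for which the scan stood in.

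Unadjusted list deviations (not relative to all miRNAs) moved with the scaling by construction. For the Sfmbt2 families in placenta 2 (main -0.036) they were 0.034 with normexp, -0.28 with the percentile over all miRNAs and -0.24 unscaled. In placenta 4 (main -0.15) they were 0.088 with quantile scaling, 0.16 with the percentile over all miRNAs, 0.32 unscaled and 0.061 with the trend removed, and in placenta 1 (main 0.036) -0.099 unscaled. A factor per array shifts a list and its random lists alike, so by construction the rank could change only through the floor. Dlk1-Dio3 stayed at percentile 99.6 in placenta 2 and 2.20 in placenta 4, both unscaled and scaled over all miRNAs, which is no further support. With normexp, the cluster of miR-322 and miR-503 lay at percentile 99.96 in placenta 4, and the epithelial list at 5.17 in placenta 2. The cause of changes other than those from scaling was not tested. Several lists changed sign, the Sfmbt2 families among them, as the values above show. Dlk1-Dio3 reversed in placenta 2 (-0.050 with the percentile over all miRNAs, -0.013 unscaled) and in placenta 4 (0.13 unscaled). The cluster of miR-322 and miR-503 reversed in placenta 4 (-0.074 with normexp, and -0.0052 to 0.093 leaving out each placenta). The epithelial list reversed in placenta 2 (0.029 with normexp). Scaling also changed other signs, for example in placenta 4 unscaled. There miR-17~92 went from -0.19 to 0.28, and the cluster from miR-290 to miR-295 from -0.18 to 0.29. The epithelial list in placenta 4, near 0 at -0.010, became 0.25 with quantile scaling, 0.30 with the percentile over all miRNAs, 0.46 unscaled, 0.13 with the brightest probe, 0.14 in the authors' table, 0.29 with the trend removed, 0.12 with negative controls subtracted, and -0.040 to 0.015 leaving out each placenta. Negative control spots had medians of 4.13 and 4.33 on the first scan and -0.43 and -0.048 on the second, so signals of a few units are not comparable across scans.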

Other observations

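In this part, the test of the scan for single miRNAs, and the brightness, scan and cell share tests of the lists, were chosen after the result was seen. Of the 196 detected miRNAs, 88 belonged to none of the lists. Among them were the 3 members of the miR-183 cluster, best known from sensory organs, chosen here after their values were seen. miR-96-5p stood at 1.73 ± 0.12 (SD, n = 4), miR-182-5p at 0.98 ± 0.14 and miR-183-5p at 0.90 ± 0.08, and together they took 1.54% ± 0.19 of the signal. miR-3107-5p, whose precursor is now counted with miR-486, an erythroid miRNA, was also chosen after its values were seen. It stood at -1.14 in placenta 2 and at -2.30, -1.81 and -2.63 in placentas 1, 3 and 4, the order of miR-451a.

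miR-721, miR-211-3p, miR-714, miR-3082-5p and miR-466i-5p were higher on the first scan than on the second by a median of 1.21 (log2). Subtracting the negative controls left a median of 1.09, which argues against the background offset between scans as the whole cause. miR-721, miR-211-3p and miR-714 differed by 0.042, 0.023 and 0.17 within the first scan and by 0.89, 0.79 and 0.83 within the second, and miR-3082-5p and miR-466i-5p by 0.79 and 0.58 within the first and by 0.24 and 0.21 within the second. An effect of the scan cannot be told apart from differences between placentas, since each placenta was in 1 scan: 79 of 196 miRNAs were fully separated by scan, against 53 and 64 for the other pairings and 65.3 by chance. miR-574-5p, chosen after its values were seen, had -1.20 and -0.57 on the first scan and -1.97 and -1.76 on the second.

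From the list shifts relative to all detected miRNAs, placenta 2 minus placenta 4 was 1.25 for blood markers, 0.34 for mesenchymal markers and 0.23 for Dlk1-Dio3, and the differences within scans summed to 1.57, 0.10 and 0.13 (with normexp, 0.62, 0.15 and 0.11, and 0.76, 0.024 and 0.068 within scans). The mesenchymal markers were 3 miR-199 products, and their sum within scans changed sign, to -0.016, with the brightness trend removed. For endothelial miR-126-3p the difference was -0.049 (-0.20 within scans), 0.086 with negative controls subtracted and 0.068 with the trend removed. For let-7, the cluster of miR-322 and miR-503 and the epithelial list, placenta 2 minus placenta 4 was -0.47, -0.51 and -0.48 (-0.44, -0.46 and -0.31 as medians of the members' differences), and the differences within scans summed to -0.37, -0.49 and -0.28. With the brightness trend removed, placenta 4 minus placenta 2 was 0.33, 0.52 and 0.57 for these 3 lists, which argues against scaling by brightness as the whole cause, and it was 0.44, 0.21 and 0.054 with normexp on the median signal and 0.32, 0.51 and 0.73 with negative controls subtracted. Over 5 settings the lowest sum within scans was 0.19 for let-7 and the cluster of miR-322 and miR-503, above the median SD in each setting. For the epithelial list it was 0.043 (normexp, median SD 0.15). Placentas 4 and 2 were picked as the extremes of these lists, so a positive sum in the main setting was built in. The median SD is also that of single miRNAs, not of a sum of list medians. The sums therefore cannot decide whether the scan was the whole cause. Within the second scan, let-7 lay at -0.0098 in placenta 3 and 0.31 in placenta 4. For these 3 lists, mesenchymal markers and Dlk1-Dio3, an effect of the scan was not excluded. A lower share of epithelial cells alone would raise markers of all other cell types alike. As medians of the members' differences, blood and mesenchymal markers stood at 1.28 and 0.37, 0.90 apart, and endothelial miR-126-3p at -0.023. The blood excess in placenta 2 was known when this comparison was chosen, so the gap was largely given in advance. These markers did not move alike, but a lower epithelial share together with a separate difference in blood was not excluded. Differences in the amount of single cell types or in stage within E11.5 may contribute, and no other biological explanation was tested.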
